A study of Homo sapiens with 27 samples.

How the data were processed

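Human bone marrow mesenchymal stromal cells were cultured towards fat or bone and collected over time, and each collection was measured as 1 single-cell RNA library with the 10x Genomics 3' assay. The deposited files hold 27 libraries. Per the labels, 16 belong to the adipogenic series and 11 to the osteogenic series. Series text describes hydrogels of low stiffness (1.5 kPa) for adipogenic culture and of high stiffness (25 to 40 kPa) for osteogenic culture, so medium and stiffness change together and their effects cannot be told apart. Cells came off hydrogels or plasticware, and which of these applies to a given library is not given in the sources used here.

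The deposited matrices hold counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Per the submitters' processing notes, reads were processed with Cell Ranger and Seurat on hg38, with versions not given in the sources used here. Every library's values were checked to be whole numbers with totals that differ between libraries. The files list 33538 genes by identifier and symbol. Coordinates came from the GENCODE v29 annotation of GRCh38, counted from 1.

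Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept, which left 34453 of 38360. Scrublet, as run in scanpy 1.11.5, called 202 of the kept cells doublets (0.586%), and these were kept except in 1 alternative. Raw UMIs of the kept cells were summed per library. For shares of cells and for classes of cells, every cell was thinned at random to 5000 UMIs, and 2017 shallower cells were left out, leaving 32436. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

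Library totals ran from 24481366 to 46520409 UMIs. The median per cell ran from 11458 to 68551 UMIs. The file names fall into 2 kinds, 19 with the word "analysis" and 8 without it, and the median UMIs per cell ran from 11458 to 37320 in the former and from 38160 to 68551 in the latter. This naming was treated as a possible batch and entered as a covariate wherever both kinds were present.

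Summed counts were tested with edgeR's quasi-likelihood F test (TMM size factors, filterByExpr with its defaults, robust fit). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The trends by day used 10 libraries per lineage, with time on the scale log2(day + 1), so that the coefficient is the fitted log2 change from day 0 to day 14. The osteogenic series runs to day 21. The lineage difference (osteogenic minus adipogenic) used the 15 libraries of days 1, 2, 3, 7, 10 and 14, with day as a factor. A model of all 20 libraries tested the interaction of lineage and day. The trend by hour used 5 adipogenic libraries of hours 0, 2, 4, 8 and 12 on the scale log2(hour + 1), with 3 residual degrees of freedom. Contrasts between the groups with 2 libraries (adipogenic days 0, 3 and 7 and osteogenic day 7) used 1 shared estimate of the spread, also with 3 residual degrees of freedom. Errors beside fitted values are standard errors derived from the F statistic.

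Cells with a UMI from at least 3 of 12 adipocyte marker genes at 5000 UMIs were called marker-high, and the others marker-low. The 12 genes are ADIPOQ, PLIN1, PLIN4, FABP4, CIDEC, CIDEA, LPL, LIPE, AQP7, GPD1, TRARG1 and CD36. Summed thinned counts of both classes were compared within libraries that had at least 20 cells of each, with library as a block and without the 12 genes. Shares of marker-high cells were related to day by Pearson's r and Spearman's rho over 4 relations, with 100000 two-sided permutations. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only.

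Folds are ratios of mean CPM, the counts of a gene scaled to a common library total, in the groups named. Where a group had no UMI of a gene, the fold is a lower bound set by 3 counts over the group, and where it had 1 to 3 UMIs the counting interval is given.

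There were 31 gene lists, 26 of functions or states of these cells and 5 of other cell types, with 480 entries that were all matched to the files, 2 of them by an earlier symbol (CYR61 and CTGF for CCN1 and CCN2). They cover adipocyte markers, adipogenic transcription factors, fatty acid and triglyceride synthesis, fatty acid oxidation, cholesterol synthesis, osteoblast markers, extracellular matrix, glucocorticoid response, cAMP response, immediate early and heat shock genes, YAP/TAZ targets, contractile and smooth muscle genes, focal adhesion and actin cytoskeleton, TGF-beta targets, BMP targets, Wnt targets and antagonists, S phase, G2/M phase, integrated stress and unfolded protein response, glycolysis and hypoxia, oxidative phosphorylation, interferon response, cytokines and matrix proteases, senescence and p53 targets, stromal progenitor surface and niche, chondrocyte markers, and markers of haematopoietic, endothelial, epithelial, skeletal muscle and neural cells. Lists were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over lists.

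The comparisons, gene lists, thresholds and rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 20 CPM, or 5 and 5 for the interaction, the duplicated days and the cell classes. It added up to 4 members of each list with the smallest p. Clone names, mitochondrially encoded genes, ribosomal protein genes and sex-linked marker genes were not named.

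The tests were tried on simulated data made from these counts, with 100 genes changed by 1 and 100 by 2 on the log2 scale. A separate list of genes was raised by 1 to try the list test. At a log2 size of 1 the share of changed genes called was 16% for the adipogenic trend, 45% for the osteogenic trend, 69% for the lineage difference, 17% for the interaction, 8% for the hours and 84% for the cell classes. At a log2 size of 2 these shares were 67%, 82%, 89%, 56%, 69% and 99%. Unchanged genes made up 4.35%, 8.16%, 2.79%, 3.90%, 14.1% and 8.68% of the calls, in the same order. In the 3 contrasts between duplicated days, 16%, 21% and 14% of genes were called at a size of 1 and 74%, 71% and 68% at a size of 2, and unchanged genes made up 15.9%, 13.5% and 13.3% of the calls. Except over the hours, more genes were called in the real data than were changed here. These shares therefore need not hold for the real calls.

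The alternatives tried were RLE size factors, DESeq2's Wald test, no filter on low counts, every barcode, at most 10% mitochondrial UMIs, doublets left out, cells thinned to 5000 UMIs, no naming covariate, 1 kind of file naming alone, linear time, a natural spline of day with 2 degrees of freedom, hour libraries added as fractions of a day, days to 14 only, marker-low cells alone, and each library left out in turn. For the classes they were at least 2 or at least 4 markers, 3000 UMIs and unthinned counts. Both libraries titled D0-5 were left out of the trends because their time is ambiguous, and 1 alternative read it as day 0.5.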

Results

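RNA was counted in single human bone marrow stromal cells sampled along 2 courses, one towards fat and one towards bone. The adipogenic series held 10 libraries by day (days 0, 3 and 7 with 2 libraries each, days 1, 2, 10 and 14 with 1), 5 by hour (hours 0, 2, 4, 8 and 12) and 1 titled D0-5. The osteogenic series held 10 libraries by day (day 7 with 2 libraries, days 0, 1, 2, 3, 5, 10, 14 and 21 with 1) and 1 titled D0-5. After filtering, a library held between 618 and 2772 cells. Labels do not say whether the libraries are separate cultures or donors, so every p-value measures only the spread between these libraries. Apart from the duplicated groups, a time point had no replicate. The labels name no uninduced course, so changes with day cannot be split between induction and time in culture.

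The first comparison asked which genes changed with day in adipogenic culture. Over 14 days the cells gained the transcripts of fat storage and lost those of division, of the contractile cytoskeleton and of epithelial markers. Of 14975 genes tested over 10 libraries, 3451 rose and 3751 fell, with 2275 rises and 2101 falls of more than 1 on the log2 scale, and 8327 genes had an unadjusted p under 0.05. A linear day scale lowered both counts, the rises more than the falls. Called genes tested within each kind of file naming kept their sign for 99.985% of those in files named with the word and 100% of those named without it, where 2822 and 2605 genes were called alone. The genes were chosen from these same libraries, so the kept signs were largely fixed in advance. Without day 0 replicate 2 the calls dropped to 1811 higher and 2195 lower. The median percent of mitochondrial UMIs per cell was 5.97 and 6.18 in the day 0 libraries. It was 9.55 and 9.96 at day 7, 10.5 at day 10 and 11.6 at day 14. The osteogenic day libraries lay between 4.94 and 5.87. Barcodes over the mitochondrial limit made up 5.88% to 13.4% in the adipogenic day libraries named with the word and 11.8% to 25.5% in those named without it.

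Adipocyte markers had the steepest rise. Of 17 measured, 16 rose and 0 fell, the same counts when adjusted over the list alone, and the median fold from day 0 to days 7 to 14 was 881.1 with 8 genes at their lower bound (list adjusted p = 1.83e-08, adjusted p = 0.436 with an estimated correlation). The adipokine ADIPOQ (ENSG00000181092, chromosome 3, 186842690 to 186858463) had no UMI at day 0 and was at least 3804.8-fold higher at days 7 to 14 (adjusted p = 2.69e-04). FABP4 (ENSG00000170323, chromosome 8, 81478419 to 81483263), a fatty acid carrier, went from 3.21 ± 1.85 CPM (SD, n = 2) to 4238.5 ± 1887.1 CPM (SD, n = 4), with a fitted log2 change of 12.66 ± 1.87 (adjusted p = 7.34e-04). The lipid droplet protein gene PLIN4 was at least 6570.3-fold higher and PLIN1 at least 3629.4-fold higher.

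Lipid synthesis rose with them. Of 17 genes of fatty acid and triglyceride synthesis, 16 rose and 0 fell, as they did adjusted over the list alone, with a median log2 change of 3.25 (list adjusted p = 2.04e-08, adjusted p = 0.428 with an estimated correlation). DGAT2, which makes triglyceride, rose by 8.35 ± 0.61 on the log2 scale (adjusted p = 6.82e-05) and ACSL1 by 5.17 ± 0.37 (adjusted p = 5.67e-05). Of 13 adipogenic transcription factors, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 2.34 (list adjusted p = 2.80e-05, adjusted p = 0.428 with an estimated correlation). CEBPA rose by 10.34 ± 1.05 (adjusted p = 1.51e-04) and PPARG by 5.47 ± 0.70 (adjusted p = 3.70e-04). Of 19 genes of cholesterol synthesis, 13 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.34 (list adjusted p = 5.57e-05, adjusted p = 0.611 with an estimated correlation). HMGCS1 rose by 2.66 ± 0.26. Glucocorticoid response genes had 7 rises and 0 falls among 15 (8 and 0 adjusted over the list alone; list adjusted p = 0.00307, adjusted p = 0.611 with an estimated correlation), with MAOA and SAMHD1 among them.

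Division fell as a block. All 22 G2/M genes and all 19 S phase genes fell, also adjusted over the list alone, with medians of -3.43 and -2.40 on the log2 scale (list adjusted p = 1.83e-08 for each, adjusted p = 0.611 for each with an estimated correlation). UBE2C, which targets mitotic proteins for destruction, went from 95.2 ± 58.0 CPM (SD, n = 2) to 6.96 ± 3.98 CPM (SD, n = 4), with a fitted change of -4.20 ± 0.52. Of 12 contractile genes, 7 fell and 0 rose with a median of -1.81, and of 16 genes of focal adhesion and the actin cytoskeleton, 12 fell and 1 rose with a median of -1.18, the same counts adjusted over the list alone (list adjusted p = 0.00144 for each, adjusted p = 0.611 for each with an estimated correlation). TPM1 changed by -3.61 ± 0.42 (adjusted p = 2.39e-04) and ACTB by -2.82 ± 0.25 (adjusted p = 1.06e-04). YAP/TAZ targets had 1 rise (F3) and 11 falls among 17, AXL among the falls, and epithelial markers had 4 falls and 0 rises among 5 measured, again unchanged when adjusted over the list alone. Their medians were -1.32 and -7.26 (list adjusted p = 0.00567 and 5.76e-04, adjusted p = 0.611 and 0.428 with an estimated correlation). KRT18 (ENSG00000111057, chromosome 12, 52948871 to 52952901) went from 359.8 ± 201.0 CPM (SD, n = 2) to 3.67 ± 1.34 CPM (SD, n = 4), and KRT19 changed by -11.99 ± 0.76 on the log2 scale. Reads shared between KRT18, or a metallothionein gene, and near-identical copies were not tested for.

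Other lists did not pass in the adipogenic trend, though single members did. Matrix genes split into 7 rises and 8 falls among 25 (9 and 8 adjusted over the list alone; list adjusted p = 0.955), COL6A1 rising by 2.12 ± 0.22 and ELN changing by -4.40. Stromal progenitor genes split into 6 rises and 5 falls among 14 (list adjusted p = 0.822), LEPR rising by 4.68 and NT5E changing by -2.76. Osteoblast markers had 7 rises and 1 fall among 17 (list adjusted p = 0.111), chondrocyte markers 5 rises and 0 falls among 9 (0.0596), immediate early genes 8 and 3 among 16 (0.135) and Wnt targets 6 and 3 among 11 (0.317). Fatty acid oxidation had 7 rises and 1 fall among 14 (list adjusted p = 0.135), BMP targets 3 and 1 among 12 (0.551), TGF-beta targets 2 and 2 among 13 (0.758), and oxidative phosphorylation 2 and 7 among 21 (0.177). Stress response genes had 5 rises and 3 falls among 15 (list adjusted p = 0.225), glycolysis 2 and 4 among 17 (0.782), interferon response 1 and 2 among 15 (0.551), cytokines 1 and 1 among 14 (0.524), and cAMP response 1 and 0 among 13 (0.524). Senescence genes had 6 rises and 4 falls among 14, with a median of 0.15 and a mean of -0.50 (list adjusted p = 0.782). Haematopoietic, endothelial, skeletal muscle and neural markers had 4, 2, 3 and 3 genes measured (list adjusted p = 0.432, 0.973, 0.560 and 0.653).

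The same question was asked of the osteogenic series. Cell cycle transcripts fell again, though their list means stayed near or above that of day 0 up to day 3. Part of the matrix, glucocorticoid response and adipocyte lists rose. Of 14793 genes tested over 10 libraries, 3064 rose and 3378 fell, 1731 and 1213 of them by more than 1 on the log2 scale, and 7799 had an unadjusted p under 0.05. Fewer genes were called on a linear day scale, with the larger drop among rises. Within the kinds of file naming 98.874% and 100% of called genes kept their sign, and 3189 and 3556 genes were called in each alone. Here too the genes were chosen from the same libraries, so the kept signs were largely fixed in advance. Without day 0, which has 1 library, the calls dropped to 1261 higher and 1683 lower.

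Among osteoblast markers 7 rose and 1 fell of 14 measured (8 and 1 adjusted over the list alone), with a median log2 change of 0.98 (list adjusted p = 0.0370, adjusted p = 0.586 with an estimated correlation). PTH1R, the parathyroid hormone receptor gene, rose by 4.77 ± 0.62 (adjusted p = 4.52e-04), and OMD had no UMI at day 0 and was at least 132.5-fold higher at days 7 to 14. RUNX2 rose by 3.25 ± 0.59 (adjusted p = 0.00245), a call that ended without day 0 (2.76, adjusted p = 0.0680). Matrix genes had 11 rises and 2 falls among 25 (12 and 2 adjusted over the list alone; median 0.83, list adjusted p = 0.0370, adjusted p = 0.691 with an estimated correlation). COL3A1 rose by 2.57 ± 0.48, and THBS2 was 14.3-fold higher at days 7 to 14 than at day 0. The call of the matrix list ended without day 1 (median 0.76) or day 2 (median 0.80). Chondrocyte markers had 6 rises and 0 falls among 10 (7 and 0 adjusted over the list alone; median 3.04, list adjusted p = 0.00603, adjusted p = 0.586 with an estimated correlation), with COL11A1 rising by 8.42 on the log2 scale (adjusted p = 8.87e-04), a 329.1-fold difference between day 0 and days 7 to 14. On a linear day scale the calls of COL11A1, OMD and RUNX2 ended, with adjusted p = 0.0664, 0.0632 and 0.0868.

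Adipocyte markers rose in the osteogenic libraries as well. Of 16 measured, 13 rose and 0 fell, also adjusted over the list alone, and the median fold was 7.65 with 6 genes at their lower bound and 4 with 1 to 3 UMIs at day 0 (list adjusted p = 4.43e-05, adjusted p = 0.586 with an estimated correlation). LEP (ENSG00000174697, chromosome 7, 128241284 to 128257628), the leptin gene, had no UMI at day 0 and reached 32.9 ± 12.7 CPM (SD, n = 4) at days 7 to 14, at least 501.5-fold higher. CFD rose by 8.38 ± 1.47 (adjusted p = 0.00217). ADIPOQ was among the 13 but reached 0.185 ± 0.168 CPM (SD, n = 4) at days 7 to 14, against 137.1 ± 89.9 CPM (SD, n = 4) in adipogenic libraries. APOE, which is not in that list, rose by 11.51 ± 2.31 (adjusted p = 0.00410). Of 12 adipogenic transcription factors, 10 rose and 0 fell with a median of 1.74, and of 15 glucocorticoid response genes, 11 rose and 0 fell with a median of 2.38, the same counts adjusted over the list alone (list adjusted p = 2.22e-04 for each, adjusted p = 0.586 for each with an estimated correlation). KLF5 rose by 1.52 and TSC22D3 by 3.13 ± 0.50. cAMP response genes had 6 rises and 1 fall among 13, also adjusted over the list alone (list adjusted p = 0.0403, adjusted p = 0.676 with an estimated correlation). That list call ended without any one of days 0, 2, 3 and 14 or day 7 replicate 1, with medians of 0.61, 2.27, 2.09, 1.32 and 1.45 against 2.20 with every library. On a linear day scale the calls of LEP, CFD, APOE and TSC22D3 ended, with adjusted p = 0.0670, 0.0647, 0.0960 and 0.0818.

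G2/M genes fell in all 22 cases and S phase genes in 18 of 19, with 0 rises and the same counts adjusted over the list alone (medians -2.21 and -1.79, list adjusted p = 3.48e-10 and 5.01e-06, adjusted p = 0.586 and 0.691 with an estimated correlation). AURKA changed by -2.69 ± 0.26 (adjusted p = 1.97e-04). The mean log2 of CPM plus 1 over the G2/M list was 5.12 at day 0, 5.09, 5.47 and 5.26 at days 1, 2 and 3, and 4.43 at day 5. Over the S phase list it was 3.90, 4.37, 4.31, 4.26 and 3.35 at the same days. Each of these days had 1 library, day 0 named without the word and the others with it. Epithelial markers had 4 falls and 0 rises among 5 (5 falls and 0 rises adjusted over the list alone; median -2.09, list adjusted p = 0.00487, adjusted p = 0.586 with an estimated correlation), and without day 0 that list call ended with a median of -0.99. KRT18 changed by -3.16 ± 0.37 (adjusted p = 4.00e-04). The largest named fall was LYPD1, at -6.66 ± 0.50. Contractile genes had 2 rises and 3 falls among 14 (list adjusted p = 0.747), focal adhesion genes 2 and 5 among 16 (0.498) and YAP/TAZ targets 1 and 6 among 17 (0.0971). ACTB changed by only -0.79 ± 0.09 (adjusted p = 2.80e-04). Fatty acid and triglyceride synthesis had 8 rises and 1 fall among 16 (10 and 1 adjusted over the list alone; list adjusted p = 0.0598), and cholesterol synthesis 1 rise and 2 falls among 19 (0.533).

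**Figure D1:**
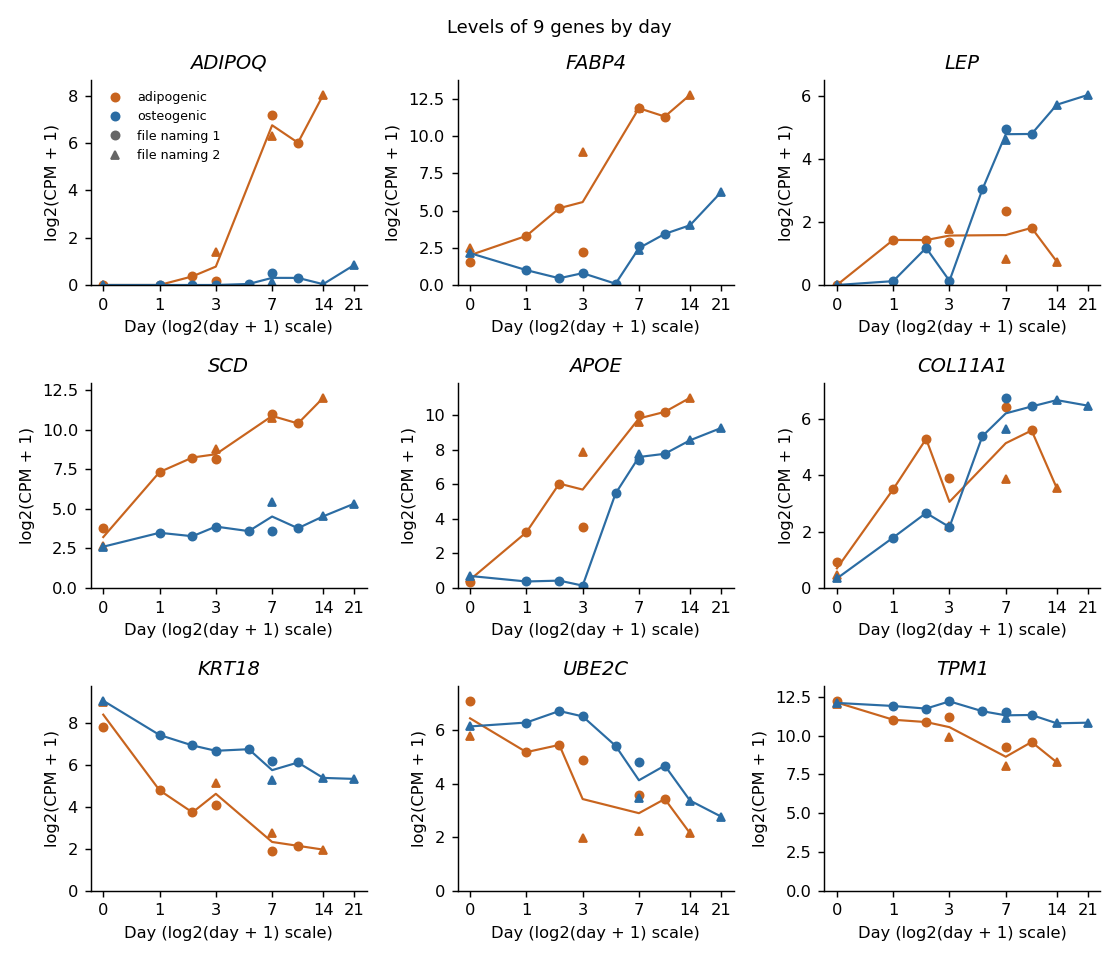
Expression of 9 genes, as log2 of CPM plus 1, against day for adipogenic and osteogenic libraries; circles are files named with the word "analysis" (file naming 1), triangles files without it (file naming 2), and lines join the means of the days. ADIPOQ averaged 137.1 CPM at days 7 to 14 in the adipogenic and 0.185 CPM in the osteogenic libraries, LEP 2.01 and 32.9 CPM, and KRT18 3.67 and 54.4 CPM.

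**Figure D2:**
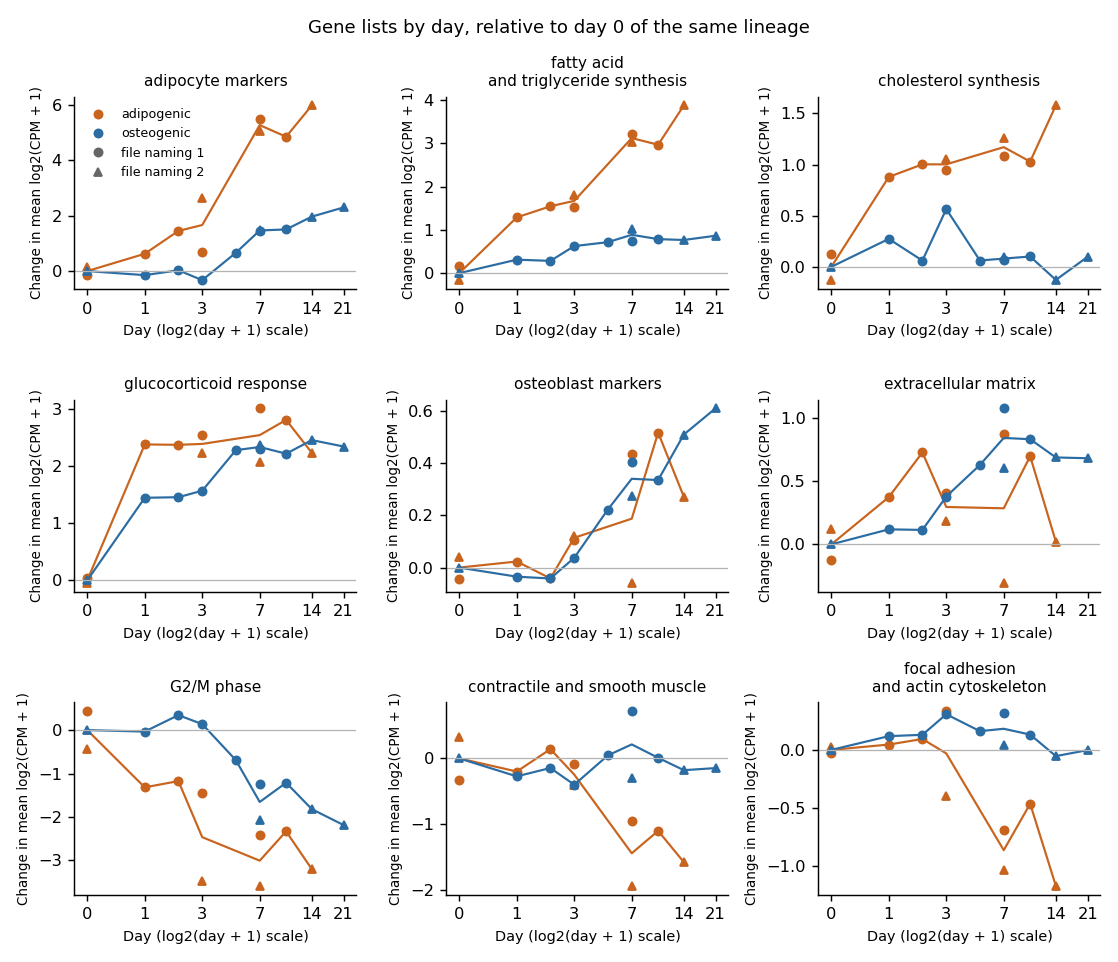
Change from day 0 in the mean log2 of CPM plus 1 over 9 gene lists against day, for both lineages; circles and triangles mark the kinds of file naming (1 with the word "analysis", 2 without it). G2/M genes went down in both lineages, after day 3 in the osteogenic one, and lipid synthesis went up in the adipogenic one.

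How far the courses differed was tested directly. Across the 14399 genes in both tests the trends went largely the same way (Pearson r = 0.805 and Spearman rho = 0.762, across genes, which are not independent replicates). Both trends rose for 1775 genes, where independent lists would share 655.9, and both fell for 2496, where 864.8 would be shared. Only 28 genes rose in the adipogenic and fell in the osteogenic trend (747.1 for independent lists), and 36 did the reverse (759.3). The interaction of lineage and day, osteogenic minus adipogenic, was called for 505 genes higher and 479 lower of 15495, with 3386 at an unadjusted p under 0.05. Of the 952 called genes tested in both trends, 62 had opposite calls. All called genes tested within each kind of file naming kept their sign, and 20 and 52 genes were called within each alone. As these genes were chosen from the same libraries, the kept signs are no separate support.

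Lipid synthesis followed different trends in the courses. Of 17 genes of fatty acid and triglyceride synthesis, 15 had a lower osteogenic slope (16 adjusted over the list alone) and 0 a higher one, with a median difference of -2.67 (list adjusted p = 6.81e-18, adjusted p = 0.00961 with an estimated correlation), the 1 list called with an estimated correlation. FASN differed by -3.33 ± 0.52 (adjusted p = 0.00182), with -3.31 and -3.87 in files named with and without the word, and LPIN1 by -2.67 ± 0.34 (adjusted p = 4.00e-04), with -2.08 and -2.94. Cholesterol synthesis had 10 lower and 0 higher among 19 (16 and 0 adjusted over the list alone; median -1.70, list adjusted p = 2.39e-13, adjusted p = 0.267 with an estimated correlation). HMGCS1 differed by -2.55 ± 0.41, with -1.61 and -2.90 within the namings. Adipocyte markers had 2 lower and 0 higher among 17 (6 and 1 adjusted over the list alone; median -4.75, list adjusted p = 4.11e-08, adjusted p = 0.267 with an estimated correlation).

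Cytoskeletal genes had the higher slope in the osteogenic course. A higher slope need not be a rise, since ACTB and most epithelial markers fell in both trends. Focal adhesion genes had 6 higher and 0 lower among 16 (11 and 0 adjusted over the list alone; median 1.11) and contractile genes 4 and 0 among 14 (8 and 0 adjusted over the list alone; median 1.97), with list adjusted p = 6.65e-08 and 2.42e-06 and adjusted p = 0.267 for each with an estimated correlation. ACTB differed by 2.04 ± 0.27 (adjusted p = 5.46e-04), with 1.56 and 2.35 within the namings. Epithelial markers had 3 higher and 0 lower among 5 (4 and 0 adjusted over the list alone; list adjusted p = 0.00273, adjusted p = 0.267 with an estimated correlation), KRT14 by 8.87 ± 1.42. YAP/TAZ targets, matrix, interferon and endothelial lists passed with 1, 3, 2 and 1 genes higher and 0, 1, 0 and 0 lower (7, 4, 4 and 3 higher and 1, 2, 1 and 0 lower adjusted over the list alone; list adjusted p = 0.00518, 0.0143, 0.0143 and 0.0148, adjusted p = 0.562, 0.594, 0.346 and 0.316 with an estimated correlation), POSTN differing by 2.97 ± 0.48. Fatty acid oxidation and adipogenic transcription factors passed with 3 and 2 genes lower and 0 higher (4 and 2 lower adjusted over the list alone; list adjusted p = 0.00579 and 0.0112, adjusted p = 0.346 and 0.527 with an estimated correlation). G2/M and S phase passed as lists (list adjusted p = 6.80e-04 and 0.0148, adjusted p = 0.781 and 0.821 with an estimated correlation) with 0 genes called by edgeR or DESeq2 and 5 and 3 higher at an unadjusted p under 0.05. Osteoblast and glucocorticoid lists did not pass (list adjusted p = 0.725 and 0.576). The list calls of S phase ended without either adipogenic day 0 library, osteogenic day 0 or day 21 (medians 0.31, 0.42, 0.46 and 0.21), that of adipogenic transcription factors without adipogenic day 0 replicate 1 (-0.41), and that of matrix genes without adipogenic day 0 replicate 2 (0.46) or day 7 replicate 1 (0.40). The ACTB call ended without the naming covariate (1.86, adjusted p = 0.0896). The interaction calls dropped to 283 higher and 303 lower without adipogenic day 0 replicate 2, to 193 and 221 without osteogenic day 0, and to 294 and 253 without osteogenic day 21, and the lower calls to 301 without osteogenic day 14. With at most 10% mitochondrial UMIs the interaction calls were 233 and 141.

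**Figure D3:**
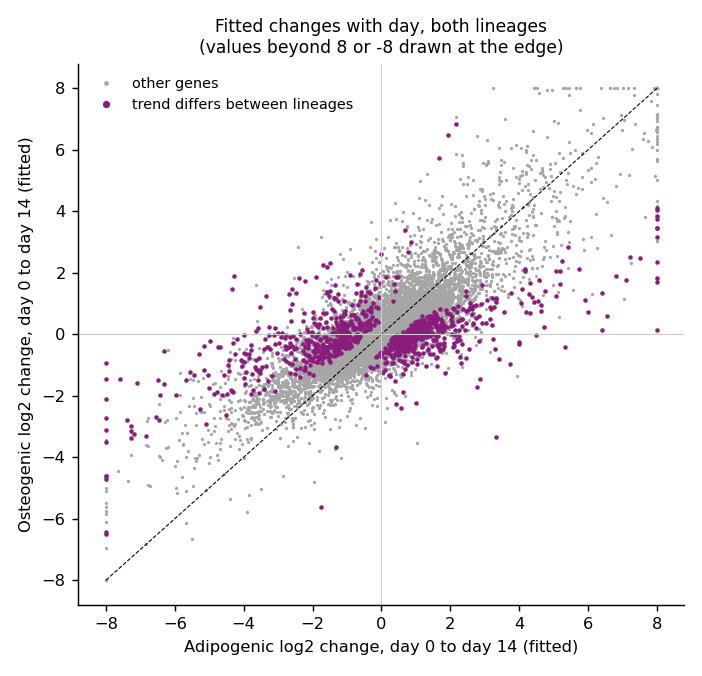
Fitted log2 change from day 0 to day 14 in the osteogenic series (vertical) against the adipogenic series (horizontal) for 14399 genes, with 952 genes of differing trend coloured and 102 genes beyond 8 or -8 drawn at the edge. Most genes lie along the diagonal, as in the correlation of 0.805.

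The average gap between the lineages was measured over shared days, with 7 osteogenic and 8 adipogenic libraries. Osteogenic libraries had more epithelial marker, cytoskeletal and cell cycle RNA and less of the lipid genes. Of 15193 genes, 3721 were higher and 3644 lower in osteogenic libraries, 1146 and 1215 of them by more than 1 on the log2 scale, with 8474 at an unadjusted p under 0.05. Lineage also sets the medium and, per the series text, the stiffness of hydrogels, so these differences cannot be split between them. Which libraries came off hydrogels is not given. The lineages also differed in the median percent of mitochondrial UMIs, at 4.94 to 5.87 in these osteogenic and 7.71 to 11.6 in these adipogenic libraries.

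Fatty acid and triglyceride synthesis was lower for 15 of 17 genes (16 adjusted over the list alone), and cholesterol synthesis for 17 of 19 (18 adjusted over the list alone), with 0 higher in each (medians -1.92 and -1.31, list adjusted p = 9.97e-08 for each, adjusted p = 0.562 for each with an estimated correlation). SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834), a desaturase, had 17.2 ± 11.9 CPM (SD, n = 7) in osteogenic and 1292.5 ± 1344.3 CPM (SD, n = 8) in adipogenic libraries, with a fitted difference of -5.71 ± 0.55 (adjusted p = 7.69e-05). Adipocyte markers were lower for 15 of 17 and higher for 0, also adjusted over the list alone (median -5.39, a median fold of 36.8, list adjusted p = 1.71e-05, adjusted p = 0.562 with an estimated correlation), ADIPOQ being 651.4-fold lower. Adipogenic transcription factors had 9 lower and 1 higher among 13, also adjusted over the list alone (list adjusted p = 0.00440, adjusted p = 0.562 with an estimated correlation). Stress response and cytokine lists were lower with 7 and 7 genes down and 0 and 1 up (7 and 8 down adjusted over the list alone; list adjusted p = 0.0436 and 0.0449, adjusted p = 0.614 and 0.562 with an estimated correlation), and each of those list calls ended at adjusted p = 0.0507 to 0.0761 when any of 8 libraries was left out. For both lists these included adipogenic days 2 and 10 and day 3 replicate 2 and osteogenic days 2, 3 and 10. Adipogenic day 7 replicate 1 and osteogenic day 7 replicate 2 also ended the stress call, and adipogenic day 3 replicate 1 and osteogenic day 1 the cytokine call.

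G2/M genes were higher in osteogenic libraries for 22 of 22 and S phase genes for 12 of 19 (14 adjusted over the list alone), with 0 lower (medians 1.36 and 0.60, list adjusted p = 2.40e-09 and 3.23e-04, adjusted p = 0.562 and 0.614 with an estimated correlation). TPX2, a spindle factor, was higher by 1.15 ± 0.07 (adjusted p = 9.28e-06). Contractile genes had 9 higher and 0 lower among 14, and focal adhesion genes 11 and 0 among 16 (12 and 0 adjusted over the list alone; list adjusted p = 0.00158 for each, adjusted p = 0.614 for each with an estimated correlation). ACTB (chromosome 7, 5527147 to 5563784) had 5963.5 ± 1858.5 CPM (SD, n = 7) against 2321.9 ± 1522.0 CPM (SD, n = 8). YAP/TAZ targets had 10 higher and 1 lower among 17 (11 and 1 adjusted over the list alone; list adjusted p = 0.00345, adjusted p = 0.602 with an estimated correlation), with ANKRD1 higher by 3.92 ± 0.39. Epithelial markers had 4 higher and 0 lower among 5 (list adjusted p = 0.00852, adjusted p = 0.562 with an estimated correlation). Osteoblast markers did not separate the lineages as a list, with 2 higher and 5 lower among 17 (list adjusted p = 0.827), nor did the matrix list, with 7 and 6 among 25 (0.827).

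The hour series asked which genes changed steadily over the first hours of adipogenic culture. Within 12 hours a few glucocorticoid response genes had risen, with metallothionein genes among them. Of 13630 genes over 5 libraries, 50 rose and 16 fell, and 2613 had an unadjusted p under 0.05. On a linear hour scale, and by DESeq2, more genes were called and more of them fell than rose. Glucocorticoid response genes had 5 rises and 0 falls among 14 (7 and 0 adjusted over the list alone; median 2.15, list adjusted p = 7.20e-08, adjusted p = 0.681 with an estimated correlation), a list call that ended without hour 0 (median 0.99). FKBP5 (ENSG00000096060, chromosome 6, 35573585 to 35728583), a chaperone of the glucocorticoid receptor, rose by 5.42 ± 0.40 (adjusted p = 0.0171), from 3.56 CPM at hour 0 to 134.9 CPM at hour 12. The metallothionein gene MT1E rose by 3.28 ± 0.18 (adjusted p = 0.00404), the growth factor gene FGF7 by 2.61 ± 0.15 (adjusted p = 0.00404), and RGMB changed by -3.13 ± 0.24 (adjusted p = 0.0164). These 4 calls held with any single library left out and ended on a linear hour scale, at adjusted p = 0.142 for FKBP5, 0.150 for MT1E, 0.0957 for FGF7 and 0.0632 for RGMB. A steady trend does not call a peak at an early hour. The mean log2 of CPM plus 1 over the cAMP response list was 2.40 at hour 0, 4.99 at hour 2, 4.06 at hour 4, 3.49 at hour 8 and 3.38 at hour 12 (trend: 0 genes called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05 among 12, list adjusted p = 0.756). Over the glucocorticoid list it was 3.93, 5.73, 5.63, 6.19 and 6.21 at the same hours. NR4A1, a cAMP response gene named here after its values were seen, had 3.25 CPM at hour 0, 331.3 CPM at hour 2 and 22.5 CPM at hour 4. With 1 library per hour, no difference between single hours was tested.

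Lipid synthesis stirred in the same hours as a list. Cholesterol synthesis had a median log2 change of 0.81 among 18 genes and fatty acid and triglyceride synthesis one of 0.86 among 16, with 0 genes called over all genes by edgeR and 9 and 8 rises adjusted over the list alone (list adjusted p = 5.28e-06 and 1.05e-04, adjusted p = 0.681 and 0.699 with an estimated correlation). At an unadjusted p under 0.05 there were 10 and 11 rises, and DESeq2 called 7 and 8. Glycolysis had 1 rise and 0 falls among 16 (3 and 0 adjusted over the list alone; list adjusted p = 0.0181, adjusted p = 0.681 with an estimated correlation), and epithelial markers 1 fall and 0 rises among 5 (3 falls adjusted over the list alone; list adjusted p = 0.0454, adjusted p = 0.681 with an estimated correlation). The glycolysis call ended without hour 12 (median 0.33), and the epithelial call without hour 0 (-0.93) or hour 12 (-1.50). The counts of genes higher and lower became 409 and 600 without hour 0, 23 and 7 without hour 4, 8 and 1 without hour 8, and 10 and 6 without hour 12.

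**Figure D4:**
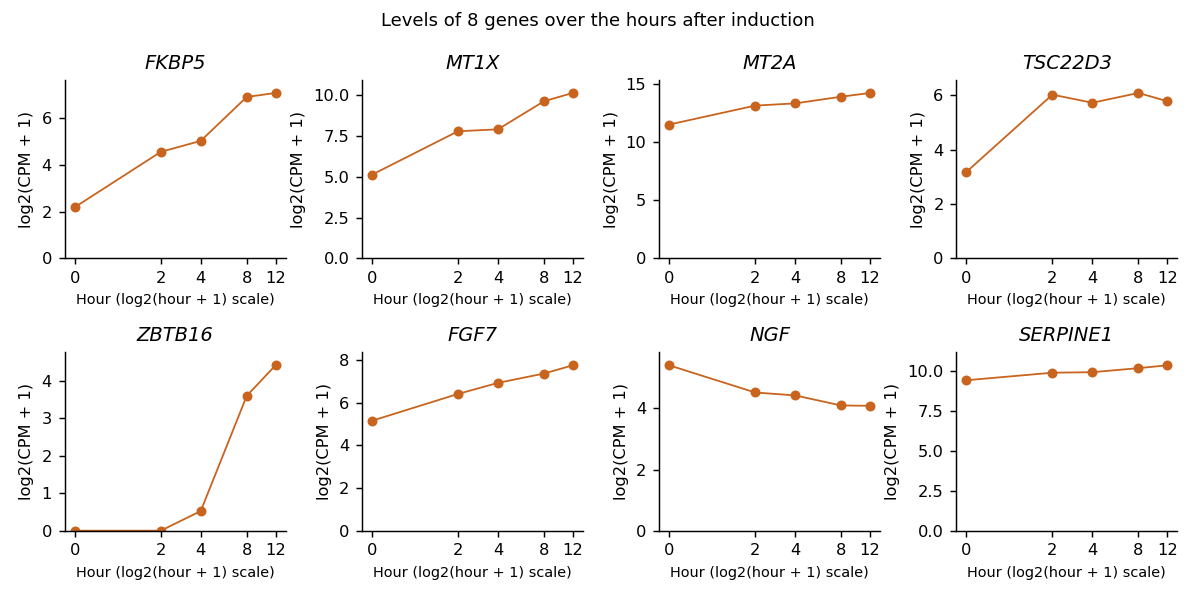
Expression of 8 genes, as log2 of CPM plus 1, against hour in the 5 adipogenic hour libraries, 1 point per library. FKBP5 went from 3.56 CPM at hour 0 to 134.9 CPM at hour 12.

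Groups with 2 libraries allowed contrasts between single days. Day 3 against day 0 of the adipogenic series had 1659 genes higher and 1692 lower of 15027, with 6020 at an unadjusted p under 0.05. Glucocorticoid response genes had 11 rises and 0 falls among 16 (12 and 0 adjusted over the list alone; median 3.14, list adjusted p = 2.82e-07, adjusted p = 0.562 with an estimated correlation). ZBTB16 had no UMI at day 0 and 36.1 ± 1.50 CPM (SD, n = 2) at day 3, at least 1000.8-fold higher (adjusted p = 0.00166), and FKBP5 rose by 5.33 ± 0.24 (adjusted p = 0.00184). G2/M and S phase fell in 22 of 22 and 19 of 19 genes, also adjusted over the list alone (list adjusted p = 3.10e-12 and 1.56e-11, adjusted p = 0.562 for each with an estimated correlation), TYMS by -2.02 ± 0.15. Adipocyte markers had 8 rises and 0 falls among 17, fatty acid synthesis 12 and 0 among 17, cholesterol synthesis 12 and 0 among 19 and adipogenic transcription factors 7 and 0 among 13, and rises numbered 12, 13, 15 and 8 adjusted over the list alone (list adjusted p = 0.00101, 1.89e-05, 1.03e-05 and 1.89e-05, adjusted p = 0.781, 0.562, 0.562 and 0.562 with an estimated correlation). CEBPD rose by 4.46 ± 0.32, and the chemokine gene CXCL1 by 4.32 ± 0.23. The counts higher and lower fell to 190 and 190 without day 0 replicate 1, 119 and 122 without day 0 replicate 2, 158 and 100 without day 3 replicate 1, and 622 and 609 without day 3 replicate 2.

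Day 7 against day 0 widened this to 3064 genes higher and 2905 lower, with 7626 at an unadjusted p under 0.05. Adipocyte markers had 16 rises and 0 falls among 17, also adjusted over the list alone (list adjusted p = 1.55e-08, adjusted p = 0.540 with an estimated correlation), with PLIN4 at least 5749.0-fold higher. LIPE, a lipase gene, rose by 5.07 ± 0.34 (adjusted p = 9.42e-04) and FASN by 2.96 ± 0.22 (adjusted p = 0.00128). Focal adhesion genes had 12 falls and 2 rises among 16 and contractile genes 7 falls and 0 rises among 14 (12 and 8 falls adjusted over the list alone; list adjusted p = 0.00181 and 9.48e-04, adjusted p = 0.606 for each with an estimated correlation). TPM1 changed by -3.48 ± 0.33. Without day 0 replicate 1, day 0 replicate 2 or day 7 replicate 2 the counts were 1301 and 1479, 1084 and 1285, or 1484 and 1401.

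Osteogenic against adipogenic day 7 had 880 genes higher and 685 lower, with 4580 at an unadjusted p under 0.05. Fatty acid and cholesterol synthesis were lower for 14 of 17 and 14 of 19 genes, with 0 higher (17 and 17 lower adjusted over the list alone; list adjusted p = 9.77e-11 and 4.68e-10, adjusted p = 0.655 for each with an estimated correlation). Focal adhesion genes were higher for 12 of 16 and contractile genes for 7 of 14, with 0 lower (14 and 11 higher adjusted over the list alone; list adjusted p = 1.33e-07 and 3.83e-07, adjusted p = 0.655 for each with an estimated correlation). FASN had 29.8 ± 4.04 CPM (SD, n = 2) against 238.3 ± 21.1 CPM (SD, n = 2), a fitted difference of -3.01 ± 0.22 (adjusted p = 0.00693), and ACTB was higher by 2.15 ± 0.21 (adjusted p = 0.01004). Without osteogenic day 7 replicate 2 the counts were 5 higher and 0 lower by edgeR, with 1296 genes lower at an unadjusted p under 0.05, and the calls of FASN (-2.74) and ACTB (2.12) ended. They were 95 and 35 without osteogenic day 7 replicate 1, where the call of ACTB (2.16) also ended, 95 and 74 without adipogenic day 7 replicate 2, and 555 and 443 without adipogenic day 7 replicate 1. Leaving out a library outside this contrast, which enters the same fit, gave 549 and 363 without adipogenic day 0 replicate 1, 528 and 353 without day 0 replicate 2, and 441 and 435 lower without day 3 replicate 1 and 2. With at most 10% mitochondrial UMIs the counts were 585 and 369. The median percent of such UMIs was 5.08 and 5.49 in the osteogenic and 9.55 and 9.96 in the adipogenic day 7 libraries.

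Cells with a UMI from at least 3 of the 12 adipocyte markers, called marker-high, were counted at 5000 UMIs per cell. They made up 53.8% of adipogenic cells at day 14, 14.9% at day 10, and 28.6% and 19.2% in the day 7 libraries, and 4.96% (exact 95% interval 3.63 to 6.60) and 0.252% (0.0305 to 0.907) in the day 3 libraries. Free RNA in a library can place such UMIs in cells that lack the transcripts. Its level was not measured, so the shares are not shares of adipocytes. Of the 311 marker-high cells at day 14, 111 had exactly 3 markers. Another 131 of the 578 cells had 2 markers and 64 had 0. With at least 4 markers the shares were 34.6% at day 14 and 2.25% in day 3 replicate 1, and with at least 2 they were 76.5% and 14.1%. Without thinning they were 90.5% at day 14, 24.6% at day 10, 67.2% and 30.6% at day 7, and 20.7% and 0.962% at day 3. At day 0, which does not measure that free RNA, 0 of 1919, 820 and 590 cells were marker-high, which allows shares of up to 0.192%, 0.449% and 0.623%. Osteogenic shares reached 1.55% at day 14 and 2.97% at day 21. They were 0.517% and 0.990% with at least 4 markers and 4.92% and 9.19% with at least 2. They were 0.476% and 1.79% at 3000 UMIs and 6.83% and 12.8% without thinning. Over 4 relations, the adipogenic share followed day with r = 0.911 (permutation p = 8.60e-04, adjusted p = 8.60e-04) and rho = 0.939 (permutation p = 2.10e-04, adjusted p = 4.20e-04) over 10 libraries. Without days 10 and 14, the values farthest from the median day, r was 0.913 (exact permutation p = 0.00218). The osteogenic share had r = 0.932 (permutation p = 6.00e-04, adjusted p = 8.00e-04) and rho = 0.947 (permutation p = 1.20e-04, adjusted p = 4.20e-04), but r = 0.667 (exact permutation p = 0.0565) and rho = 0.893 (exact permutation p = 0.00655) without days 14 and 21. Among 6 libraries named with the word, which include neither of these, r was 0.889 in the adipogenic and 0.955 in the osteogenic series, and the 4 named without it were too few. Hour libraries did not enter these relations. Hour 12 had a share of 0.939% (exact 95% interval 0.451 to 1.72), against 0.229% at adipogenic day 1 and 0.765% at day 2.

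**Figure D5:**
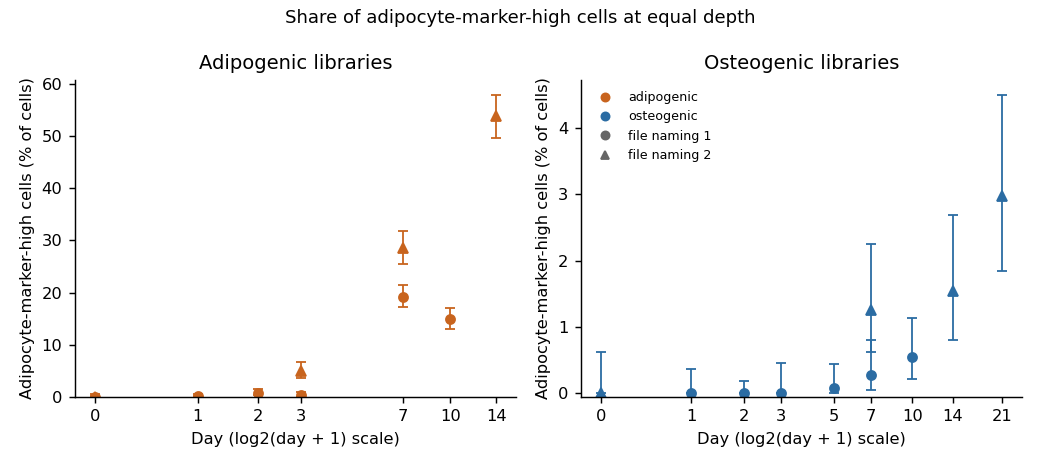
Percent of cells that were marker-high at 5000 UMIs per cell against day, with exact 95% intervals, for adipogenic and osteogenic libraries; circles are files named with the word "analysis" (file naming 1) and triangles files without it (file naming 2). The adipogenic share reached 53.8% at day 14 and the osteogenic share 2.97% at day 21.

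Within 5 adipogenic libraries, marker-high cells were compared with the marker-low ones. Marker-high cells carried more RNA of the lists of fatty acid synthesis, fatty acid oxidation and cholesterol synthesis and less of those of matrix and contractile genes, each as a share of the same 5000 UMIs per cell. Of 9049 genes, 919 were higher and 905 lower, with 2913 at an unadjusted p under 0.05. Fatty acid and triglyceride synthesis was higher for 17 of 17 genes, fatty acid oxidation for 10 of 13 and cholesterol synthesis for 13 of 17, with 0 lower (17, 10 and 14 higher and 0, 1 and 0 lower adjusted over the list alone; list adjusted p = 4.43e-17, 3.12e-05 and 3.33e-07, adjusted p = 0.427 for each with an estimated correlation). The oxidation gene lower over its list alone was CPT1A, named here after its values were seen, with 6.68 ± 6.23 against 9.89 ± 3.16 CPM (SD, n = 5; adjusted p = 0.0708 over all genes). CEBPA had 197.2 ± 135.3 CPM (SD, n = 5) against 8.29 ± 3.29 CPM and was higher in 5 of 5 libraries (log2 4.52 ± 0.29, adjusted p = 1.23e-05). ACSL1 was higher by 2.67 ± 0.18. Adipogenic transcription factors had 7 higher and 1 lower among 12, the adipocyte markers outside the class definition 3 and 0 among 4, and oxidative phosphorylation 7 and 1 among 21 (8, 4 and 11 higher adjusted over the list alone; list adjusted p = 5.39e-04, 6.11e-05 and 0.00134, adjusted p = 0.427, 0.427 and 0.462 with an estimated correlation). Matrix genes were lower for 11 of 24, contractile genes for 8 of 9, focal adhesion genes for 10 of 16 and YAP/TAZ targets for 10 of 16, with 0, 0, 0 and 1 higher (15, 9, 11 and 12 lower adjusted over the list alone; list adjusted p = 5.97e-06, 9.01e-06, 1.27e-05 and 2.37e-04, adjusted p = 0.427 for each with an estimated correlation). The BMP antagonist gene GREM1 was lower by -3.22 ± 0.19 on the log2 scale (adjusted p = 9.34e-08), in 5 of 5 libraries, with 17.3 ± 7.82 against 186.3 ± 128.8 CPM. Cytokines had 7 lower and 1 higher among 10, also adjusted over the list alone (list adjusted p = 0.0117, adjusted p = 0.427 with an estimated correlation). Glucocorticoid genes had 6 lower and 1 higher among 15 and S phase genes 3 and 0 among 9 (8 and 3 lower adjusted over the list alone; list adjusted p = 0.0210 and 0.0252, adjusted p = 0.427 for each with an estimated correlation), calls that ended without day 7 replicate 2 (medians -0.52 and -0.68) and, for S phase, also without day 7 replicate 1 (-0.48) or day 10 (-0.61). Without day 10 the counts were 575 higher and 490 lower, and without day 7 replicate 2 they were 583 and 520.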

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

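Tests chosen only after the result was seen were those of carried-over RNA, of marker-high cells alone, of file naming, of depth in the day 3 libraries, and of other assignments for the adipogenic trend, the osteogenic trend and the lineage difference. For 2 tests the rule for reading the value was also changed after that value was known, and both earlier readings are given.

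The courses differed by a test of the difference itself, with 984 genes called for an interaction of lineage and day. Fatty acid and triglyceride synthesis passed as a list even with an estimated correlation, at an adjusted p of 0.00961. Of 100 assignments of lineage to the 20 libraries, the real one included, 1 gave as many genes, and the highest other gave 6. These assignments also broke up the average difference between the lineages, so they cannot decide whether the trends differ. Lineage, medium and stiffness stay together as the untested sources of the difference.

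Both libraries titled D0-5 showed glucocorticoid targets above day 0, in data that entered no comparison except in 1 alternative. FKBP5 had 268.5 CPM in the adipogenic and 81.9 CPM in the osteogenic library, against 3.97 ± 0.72 CPM (SD, n = 2) and 2.97 CPM at day 0. ZBTB16 had 18.2 CPM and 3.86 CPM, against no UMI in the adipogenic day 0 libraries and 0.0218 CPM in the osteogenic one. The time that D0-5 stands for is ambiguous, and no explanation was tested.

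The first pattern weighed was the rise of adipocyte markers in osteogenic libraries, where 13 list genes rose. RNA or cells carried over from adipogenic libraries would bring each gene in proportion to its adipogenic rise. The osteogenic rise of ADIPOQ was 0.135% of its adipogenic rise, and 8 genes lay over 10 times above that fraction. LEP (1639.4%), CFD (111.7%), CIDEC (31.0%), RBP4 (12.9%) and PLIN1 (6.21%) lay far above it, which argues against carry-over for these. TRARG1 (2.60%), G0S2 (2.15%) and LPL (1.69%) lay nearer the cut. The ADIPOQ rise they were set against was only 0.185 CPM, so carry-over stays open for them. For the 5 within 10 times, ADIPOQ, PLIN4, FABP4, AQP7 and GPD1, carry-over cannot be told apart from a small rise of their own, because they were grouped by that fraction.

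A few marker-high cells alone could also carry the rise of adipocyte markers. Of the list genes that do not define the class, 4 of 4 were still higher with day in marker-low cells. LEP rose by 8.19, CFD by 9.22, G0S2 by 5.84 and RBP4 by 3.73 on the log2 scale (adjusted p = 0.00231, 0.0106, 0.0317 and 0.0239). The classes were set on thinned counts. At osteogenic days 14 and 21, 1.55% and 2.97% of cells were marker-high with thinning, but 6.83% and 12.8% without it. The marker-low class thus still held cells that are marker-high at full depth. This test therefore cannot decide on marker-high cells alone for these 4 genes. The other 9 define the class, so the filter itself lowers them and the explanation stays open: PLIN4 (5.31) and CIDEC (5.35) still passed, PLIN1 went from 8.48 in all cells to 5.93 (adjusted p = 0.0527) and FABP4 from 4.03 to 2.54 (adjusted p = 0.223), and ADIPOQ, LPL, AQP7, GPD1 and TRARG1 had too few counts. The first rule asked for 1 in 2 of all 13 genes, which the 6 that passed do not reach, and would have favoured marker-high cells alone; it was replaced after the values were known, first by a rule over the 8 tested genes and then by one over those outside the class. Free RNA from marker-high cells could also reach marker-low ones, and this was not tested, so a partial adipocyte state spread over the osteogenic cells remains a hypothesis.

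The second pattern was the fall of epithelial markers in both lineages. Epithelial cells mixed into the day 0 libraries would be a minority, put at no more than 20% of cells with a KRT18 UMI. At 5000 UMIs per cell KRT18 was seen in 49.1% (exact 95% interval 46.8 to 51.4), 72.4% and 70.5% of cells of the day 0 libraries, against 1.09% to 2.92% in adipogenic and 11.6% to 16.8% in osteogenic libraries of days 7 to 14, while EPCAM and CDH1 reached at most 0.122%. The rule written beforehand asked for over 50% in every library, so by it the value of 49.1% left the mixture undecided. Every day 0 share lay above the bound of 20%. That bound was assumed, and reading against it alone was adopted after the value was known. Free RNA could add KRT18 UMIs to cells that lack the transcript, and this was not tested, so the mixture stays undecided. A batch that follows the file naming was tested for KRT18 and KRT19, where 8 of 8 of their trends within naming and lineage were below 0. Both genes were chosen for their falls in these same libraries, in fits that already held the naming as a covariate. The signs were therefore largely fixed in advance and do not decide on such a batch. That test read only signs and covered no other epithelial marker.

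The third pattern was the gap between the adipogenic day 3 libraries, with 4.96% marker-high cells in replicate 1 and 0.252% in replicate 2. Depth per cell is argued against, since at 5000 UMIs per cell the lower 95% bound of replicate 1 was 3.63% and the upper bound of replicate 2 was 0.907%. A batch that follows the file naming cannot be told apart from other causes (exact two-sided sign test over 3 duplicated days, p = 0.25, the smallest that 3 days allow). An earlier true day for replicate 2 cannot be told apart either: its position along the trend fitted without day 3 was 0.459, between day 1 at 0.380 and day 2 at 0.519, with replicate 1 at 0.703. Positions did not order every known day, since day 10 lay at 0.81, below day 7 at 0.898 and 0.9. A slower culture would give replicate 2 the same position, and neither free RNA that differs between the day 3 libraries nor any biological explanation was tested.

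Counts of called genes were compared with those of other assignments of the same libraries. For the adipogenic trend 1 of 100 assignments of days reached the real 7202, the highest other giving 4010. For the osteogenic trend 1 of 100 reached 6442, the highest other giving 0 genes by edgeR with at most 3516 at an unadjusted p under 0.05. Chance is thus unlikely for both but not excluded, since 100 assignments cannot show a share under 1 in 100. The adipogenic assignment that called 4010 had days correlated with the real ones at 0.859. For the lineage difference 1 of 100 reached 7365, and the highest other, at 5906, was close to the mirror image of the real one (correlation -0.875), a structure of the samples rather than noise. For the hours 1 of 100 reached 66, and the highest other gave 52 with hours correlated with the real ones at 0.967. With 1 library per hour and a count that moved widely when single libraries were left out, this rank does not settle chance. For the cell classes 1 of 16 swaps gave the real 1824 and the highest other gave 464, and 16 swaps are too few for a share under 0.05.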

How the results depend on the processing

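Alternatives chosen only after the data were seen were leaving out adipogenic day 3 replicate 2 together with day 14, and marker-low cells alone for the osteogenic trend. No paired analysis was possible because the labels number only the second library of a group, so no number links libraries of different groups; the blocks by library for the cell classes and by file naming use no such number. A spline gave no direction and is counted as calls of either sign.

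No count and no named gene or list reversed. Of 5871 values of named genes over all alternatives, 5590 (95.2%) kept their direction and side of the threshold, and of 5472 list values 5170 (94.5%) did. A gene that was no longer tested in an alternative is not counted. Named genes were also chosen largely for their calls in these libraries, which favours such agreement. With 1 library left out, 134 gene values lost their call, and 67 list values gained and 43 lost one. In the other settings 147 gene values lost their call, and 66 list values gained and 126 lost one, 93 of them with an estimated correlation.

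Pairs give genes higher and lower; the cause of a moved count was not tested unless stated. Cells thinned to 5000 UMIs gave 2274 higher for the adipogenic trend, 1883 and 2243 for the osteogenic trend, 2331 and 2192 for the lineage difference, 219 and 134 for the interaction, 97 and 51 for the hours, 1098 lower for day 3 against day 0, 2005 higher for day 7 against day 0, and 391 lower between lineages at day 7. Thinning leaves fewer counts, which lowers power, though the hour counts went up. A linear day scale gave 1582 and 2151 for the adipogenic and 1045 and 1859 for the osteogenic trend, and a linear hour scale 241 and 297.

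Files named with the word alone gave 1276 and 1546 for the adipogenic trend, 1512 and 1677 for the osteogenic trend, and 18 and 2 for the interaction. Files named without it gave 1090 and 1515, 1633 and 1923, and 31 and 21. These settings have fewer libraries. Without the naming covariate the interaction had 244 and 270, and day 3 against day 0 had 1080 lower. Marker-low cells alone gave 1944 and 2438 for the adipogenic trend, 1855 and 2202 for the osteogenic trend, and 2226 and 2064 for the lineage difference, from thinned counts. DESeq2 gave 846 and 764 for the interaction, 483 and 511 for the hours, and 1562 and 1198 between lineages at day 7. Without a filter on low counts the interaction had 305 lower and the hours 182 and 154. With at most 10% mitochondrial UMIs the interaction had 233 and 141 and the day 7 lineage contrast 585 and 369.

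An estimated correlation left 0 lists called by camera in every comparison except 1 in the interaction, where a preset correlation had called 11 in the adipogenic trend, 10 in the osteogenic trend, 12 in the lineage difference, 14 in the interaction, 5 over the hours, 9, 11 and 9 in the duplicated days and 13 between the classes. The list results thus hold under the preset correlation alone, apart from fatty acid and triglyceride synthesis in the interaction.

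With each library left out in turn, genes higher ranged from 1811 to 3522 and lower from 2195 to 3755 for the adipogenic trend, 1261 to 3476 and 1683 to 3596 for the osteogenic trend, 3063 to 3692 and 2935 to 3629 for the lineage difference, 193 to 587 and 221 to 544 for the interaction, and 8 to 409 and 1 to 600 for the hours. They ranged from 119 to 1736 and 100 to 1796 for day 3 against day 0, 1084 to 2691 and 1285 to 2706 for day 7 against day 0, 5 to 718 and 0 to 443 between lineages at day 7 (the 0 by edgeR, without osteogenic day 7 replicate 2, with 1296 genes lower at an unadjusted p under 0.05), and 575 to 1030 and 490 to 977 for the classes. Where a group kept 1 library, it was assumed to vary like the others. The relation of the marker-high share with day ranged from r = 0.826 to 0.972 and rho = 0.915 to 0.966 in the adipogenic series and from r = 0.834 to 0.953 and rho = 0.926 to 0.957 in the osteogenic series.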

Other observations

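The tests of file naming and of library pairs were chosen only after the data were seen. MT1X and PDK4 rose early in adipogenic culture but on few libraries. MT1X went up 33.2-fold and the pyruvate dehydrogenase kinase gene PDK4 50.1-fold from hour 0 to hour 12 (1 library each). The call of MT1X ended without hour 8 (fitted log2 change 4.89) or hour 12 (5.11) and on a linear hour scale (4.27), and that of PDK4 without hour 4 (6.33) or hour 12 (6.48). CIDEC, a lipid droplet gene, had no UMI at hour 0 and was at least 63.4-fold higher at hour 12 (adjusted p = 0.0171), but it was too sparse to be tested without hour 8 or hour 12.

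Genes outside the bone and fat lists also rose with day in the osteogenic libraries. CADM3 had no UMI at day 0 and was at least 453.7-fold higher at days 7 to 14 (adjusted p = 1.65e-04). APOD, with 1 UMI at day 0, was 1322.2-fold higher (counting interval 237.3 to 52226), and PTGDS 212.8-fold. LEPR, a receptor of marrow stroma, rose by 5.18 ± 0.76 in the osteogenic and by 4.68 in the adipogenic trend. On a linear day scale the osteogenic calls of PTGDS (adjusted p = 0.0709) and LEPR (adjusted p = 0.0612) ended. CXCL6, a chemokine gene, was 34.6-fold higher at adipogenic day 3 and 41.4-fold at day 7 than at day 0.

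The kinds of file naming were compared within the duplicated days. Of 15027 genes, edgeR called 0 higher and 0 lower in files named without the word, with 1991 at an unadjusted p under 0.05, while DESeq2 called 134 higher and 344 lower. At a preset correlation 12 lists were called. In files named without the word, interferon response (adjusted p = 8.24e-05) and adipogenic transcription factors (0.0203) were higher. G2/M (4.81e-19), S phase (1.49e-11), immediate early and TGF-beta target genes (2.00e-04 for each), focal adhesion (8.84e-04), matrix (0.00130), contractile (0.00238), oxidative phosphorylation (0.00361), BMP target (0.0211) and glucocorticoid response genes (0.0385) were lower. With an estimated correlation these 12 lists had adjusted p = 0.522 to 0.619. No pair of libraries matched within sampling noise, the closest being the osteogenic D0-5 and day 1 libraries with a chi-square of 10.5 per degree of freedom, and shared barcodes numbered 0 to 4.

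The libraries titled D0-5 had 0 marker-high cells among 1439 and 1746. KRT18 was seen in 9.03% of adipogenic and 36.4% of osteogenic D0-5 cells at 5000 UMIs, between the shares at day 0 and those at late days.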
